A study of Homo sapiens with 8 samples.

How the data were processed

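Cells of the human embryonic stem cell line H1 were differentiated towards cardiomyocytes, and cells of days 0, 2, 4, 6 and 8 together with day 15 were mixed and profiled by droplet single-cell RNA sequencing with version 2 of the 10x Genomics chemistry. Cells were grown on Matrigel in Essential 8 medium to confluence and passed through a 70 μm strainer. The series lists 8 samples under 1 label. The deposited matrix holds UMI counts (unit: counts), whole numbers per gene and barcode, for 60658 genes and 737280 barcodes. All barcodes share the suffix 1, so no cell can be assigned to a sample or a day, and the matrix was handled as 1 sample. No replicates exist at the level of the analysis, no paired analysis was possible because the 8 samples form 1 group and are not separable in the matrix, and no p-values were computed.

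The submitters' processing notes name Cell Ranger, Seurat and the genome build hg19 without versions or roles, and the matrix header names Cell Ranger 4 (per the file headers). The annotation release and the treatment of reads shared between gene copies are not given in the sources used here. The matrix is unfiltered: it holds the whole barcode list. Genes with near-identical copies, such as CFC1, GSTA2, HBA1, HLA-DPB2, MT1X, KRT8 and KRT18, therefore carry an unknown share of reads from or to their copies.

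Cells were called by the order-of-magnitude rule, at 10% of the 99th percentile of the UMI totals of the top barcodes, which gave a threshold of 5016 UMIs and 7393 barcodes. Barcodes with fewer than 500 genes (0) or more than 25% mitochondrial UMIs (13) were left out. Scrublet, run through scanpy with an expected doublet share of 6%, scored 7380 barcodes, and the 354 called doublets (4.80%) were removed. This left 7026 cells. Doublets between cells of the same class escape this filter, and the residual doublet share is not known. Free RNA was measured in 40546 barcodes with at least 100 and under 450 UMIs, which held 12653370 UMIs. The share of free RNA in each class was estimated from TTR and APOA2, endoderm genes, or for endoderm-like cells from MYH6 and MYL3. It was 3.54% for pluripotent-like, 3.49% for primitive streak-like, 5.43% for cardiac mesoderm-like and 6.45% for cardiomyocyte-like cells.

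Counts were scaled to 10000 UMIs per cell and logged. The 1500 most variable genes, 30 principal components, 15 neighbours, a shared-neighbour graph and Leiden clustering at resolution 1.0 gave the clusters. The fixed gene lists, mitochondrial and ribosomal protein genes, duplicated symbols and 50% of the other genes at random were kept out of the clustering genes. In all, 31703 genes were held out. Genes used for clustering or as markers describe classes and are not counted as results. Marker genes of 13 classes and 24 gene lists were fixed before the data were examined. A cluster took the class with the highest mean log2 fold of its markers (pseudocount 10), if at least 3 markers were at 20 CPM or more and 2-fold over all other cells, at least 1 stood among the 10 top genes of the cluster (30 CPM or more), and no other class had more markers there. These naming thresholds were set after the data were seen. The markers PECAM1 and TBXT and the list members CD24, ERO1L, SC4MOL and SC5DL, 6 symbols in all, matched no symbol and were not analysed under these names. TBXT and SC5DL are other names of T and SC5D, which were analysed.

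UMIs were summed per class and given as CPM (counts per 1000000) with exact Poisson intervals. Folds are ratios of CPM plus 1. Ratios of genes with 1 to 3 counts in a class are given as raw ratios with conditional binomial intervals, and genes without counts as bounds against a floor of 3 counts over the class. Shares have exact binomial intervals. All intervals are at 95% and cover counting error only, not variation between cultures. A list member counted as measured at 5 CPM or more in either class, and as higher or lower at 2-fold. List medians were set beside the medians of 10000 random lists of the same size drawn from 20 bins of level, as a description of these classes without a test. Of the 72 list and step pairs, 14 had a median of at least 2-fold.

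Comparisons followed the order pluripotent, primitive streak, cardiac mesoderm, cardiomyocyte (3 steps), with pluripotent-like against cardiac mesoderm-like and cardiomyocyte-like cells in addition, and each side class against all other cells. The comparisons planned between cardiomyocyte-like and cardiac progenitor-like cells were made with cardiac mesoderm-like cells, since no cluster took the progenitor name. Named genes are the 10 with the largest fold in each direction among genes left out of clustering, at 50 CPM or more in the higher class and with a ratio interval beyond 2-fold, without mitochondrial and ribosomal protein genes, and the leading members of each list. For classes off the route the first 4 on the higher side are named. The values of a few list members and 1 further observation are not reported here.

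The computation was tested on simulated Poisson counts for each step, with changed genes drawn from those at 50 CPM or more. Variation between cells, free RNA and cells in the wrong class were not simulated for the steps. The rates therefore check the computation and do not measure its accuracy on these data. Intervals held the true ratio for 95.4% of genes in the step from pluripotent-like to primitive streak-like cells, 95.6% in the step to cardiac mesoderm-like and 95.7% in the step to cardiomyocyte-like cells. In each step the naming rule for genes took 100% of genes set 4-, 8- or 16-fold apart, 0% of those at 1.5-fold and 0 unchanged genes. Of 200 unchanged lists 5.5%, 6.5% and 6.5% fell outside the central 95% of random lists. In a simulation of 4 classes, 100.0% of cells fell into a cluster of their own class.

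Alternatives changed the UMI threshold (1000 UMIs, or a threshold multiplied by 2), the mitochondrial limit (10%, or none), the removal of doublets, the clustering genes (drawn from all genes, or 3000), the resolution (0.5 and 2.0), the principal components (15), free RNA (subtracted), the scaling (totals without mitochondrial and ribosomal protein genes, or median ratios), the pseudocount (10) and the lowest level of a list member (10 CPM). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 and igraph 0.11.9 were used.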

Results

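H1 cells, an established human embryonic stem cell line, were taken towards cardiomyocytes by timed control of Wnt signalling. CHIR99021, an inhibitor of GSK3 that turns on Wnt signalling, was given at 8 μM on day 0. Wnt-C59, which blocks the secretion of Wnt proteins, followed at 2 μM on day 2, and B27 supplement without insulin was added on day 4. Cells of 6 time points from day 0 to day 15 were pooled into an artificial tissue and profiled by droplet single-cell RNA sequencing, which counts RNA molecules through unique molecular identifiers (UMIs). The series lists 8 samples of this pool under 1 label. Their counts are held in 1 matrix whose barcodes carry neither a day nor a sample, so the matrix was treated as 1 sample without replicates. No difference below has a replicate check, no test was run, and every interval is a 95% interval that covers counting error only.

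The matrix held 165571388 UMIs over 60658 genes. After filtering, 7026 cells with 131075336 UMIs remained, 79.2% of the total. A kept cell had a median of 15787 UMIs, from 5028 to 83020, and a median of 3710 genes. The median mitochondrial share was 3.29%. Barcodes with at least 100 and under 450 UMIs, 40546 in number, were read as empty droplets whose RNA floated free in the suspension, and their levels served as background.

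The study made this pool to test the inference of gene regulatory networks on cardiac differentiation, and the comparisons here follow the route from pluripotent cells to cardiomyocytes. The order of classes on this route was assumed and not tested, since no barcode carries a day. Clusters were named from marker genes fixed before the data were examined, so each name is rebuilt and carries "-like". The pool was mixed in proportions that are not given in the sources used here, and shares describe this pool only. Pluripotent-like cells, with POU5F1 and TDGF1, numbered 1356, or 19.3% of kept cells (exact binomial interval 18.4 to 20.2%). Primitive streak-like cells, with MIXL1, numbered 1065 in 2 clusters, or 15.2% (14.3 to 16.02%). Cardiac mesoderm-like cells, with HAND1 and TMEM88, numbered 850 in 2 clusters, or 12.1% (11.3 to 12.9%). Their smaller cluster of 188 cells held MESP1 at 82.9 CPM (counts per 1000000), and the larger of 662 cells at 6.07 CPM. The primitive streak-like clusters held MESP1 at 5.71 and 16.8 CPM. In the larger cardiac mesoderm-like cluster the mesoderm markers APLNR (28.6 CPM) and DLL3 (7.77 CPM) were below both primitive streak-like clusters. Those held APLNR at 242 and 139 CPM and DLL3 at 77.3 and 44.8 CPM. PDGFRA, LGR4 and KDR were above both, as were HAND1 and TMEM88. Of the streak markers, T was at 79.5 and 126 CPM in the primitive streak-like clusters and at most 1.17 CPM in the cardiac mesoderm-like clusters. Others went the other way. EOMES (5.47 and 6.53 CPM) and LHX1 (4.12 and 0.221 CPM) reached 25.5 and 60.4 CPM in the smaller cardiac mesoderm-like cluster. NODAL (13.2 and 5.75 CPM) reached 102.5 CPM in the larger. Cardiomyocyte-like cells, with TNNT2, TTN and NKX2-5, numbered 235, or 3.35% (2.94 to 3.79%). Their cluster also held cardiac progenitor markers, with MEF2C at 277.5 CPM, HAND2 at 69.4 CPM and ISL1 at 62.8 CPM. NKX2-5 stood on both marker lists, while the progenitor markers TBX20 and RGS13 were at 1.39 and 0 CPM. The mean log2 fold of the progenitor markers was second highest in this cluster, at 1.85 after 3.58 for cardiomyocyte markers. No cluster was named cardiac progenitor-like or smooth muscle-like. Names were given to whole clusters, so the share of such cells in the pool is not known. The share of cardiac mesoderm-like cells was 6.75% at a doubled UMI threshold, and that of cardiomyocyte-like cells 5.94% at a mitochondrial limit of 10%. The cardiomyocyte-like class was therefore compared with cardiac mesoderm-like cells, the nearest class present on the fixed order of the route. Nearness in expression was not ranked.

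A further 7 classes lay off this route: 637 epicardial-like (9.07%), 466 neuroectoderm-like (6.63%), 247 fibroblast or stromal-like (3.52%), 242 definitive endoderm-like (3.44%), 91 surface ectoderm or amnion-like (1.30%), 82 endothelial-like (1.17%) and 20 blood-like cells (0.285%). The fibroblast or stromal-like share was 9.58% with 15 principal components and 6.22% at a clustering resolution of 0.5, and the surface ectoderm or amnion-like share 3.49% at a resolution of 2.0. Another 1735 cells, 24.7% (23.7 to 25.7%), fell into 5 clusters that met no name. The largest of these clusters, with 803 cells, also held HAND1 and TMEM88. Its cells count neither in the cardiac mesoderm-like share nor in the comparisons with that class. Median depth differed between classes, from 30045 UMIs per pluripotent-like cell and 23651 per primitive streak-like cell to 13544 and 11114 in the cardiac mesoderm-like and cardiomyocyte-like classes. Levels below are UMI sums per class in CPM, and folds are of CPM plus 1.

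**Figure D1:**
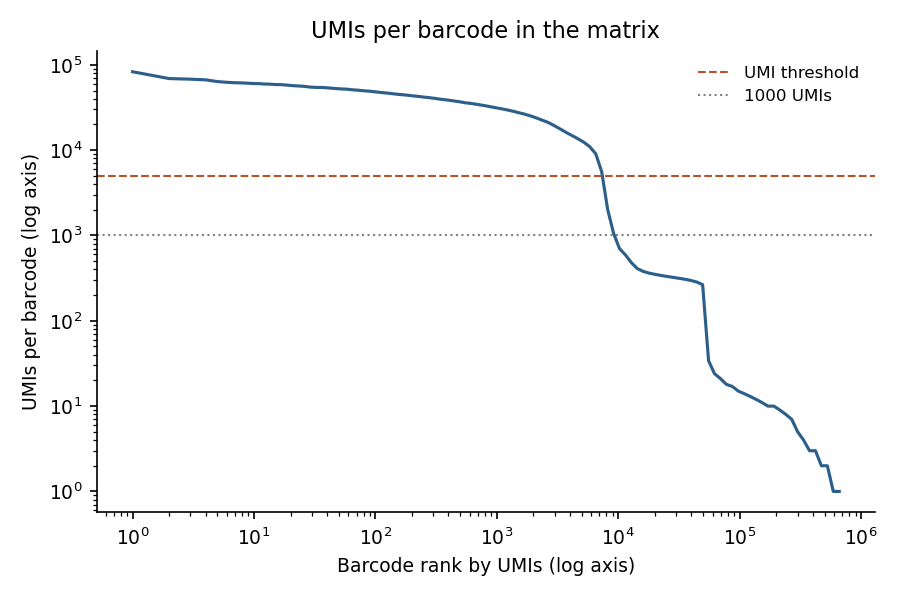
UMIs per barcode against barcode rank, both on log axes, for the 660513 barcodes with at least 1 UMI. The dashed line marks the threshold of 5016 UMIs that 7393 barcodes reached, and the dotted line marks 1000 UMIs.

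**Figure D2:**
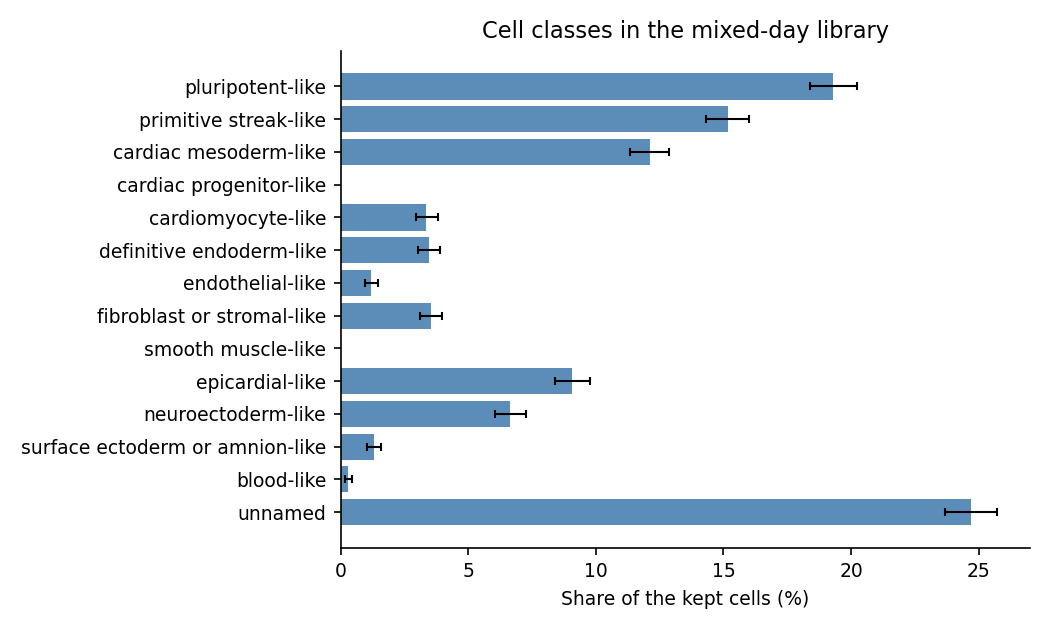
Share of the 7026 kept cells in each class, in percent, with exact 95% binomial intervals that cover counting error only, drawn for classes with cells. The pluripotent-like class held 19.3%, the cardiomyocyte-like class 3.35% and the unnamed clusters 24.7%.

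Primitive streak-like cells were set against pluripotent-like cells to ask what marks the class placed after them on the assumed route. Most measured Wnt feedback and target genes and all measured HOX genes were higher in primitive streak-like cells, while most measured pluripotency-associated genes and 11 of 18 epithelial genes were lower. DKK1, a secreted Wnt inhibitor that Wnt signalling itself induces, was at 1165 CPM (1151 to 1178) against 8.71 CPM (7.82 to 9.66), 120.1-fold higher. CDX1 and CDX2, homeobox genes of the posterior embryo, were at 167 CPM (162 to 172) against 1.25 CPM (0.931 to 1.64) and at 117 against 0.834 CPM. RSPO3, which amplifies Wnt signalling, was 78.8-fold higher, and CXCR4, a chemokine receptor of migrating mesendoderm, was at 211 against 3.09 CPM. These levels pool the primitive streak-like clusters. DKK1 and CDX1 were among the 10 top genes of both. CXCR4, and CITED1 named below, were among those of the larger cluster only, and CDX2, WNT5B and HES7 of the smaller only.

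Of 25 measured Wnt feedback and target genes, 21 were at least 2-fold higher and 3 at least 2-fold lower in primitive streak-like cells. Over all 30 listed genes the count of higher members was 23. The median log2 fold was 3.52, while the central 95% of matched random lists ran from -0.29 to 0.23. WNT5B, a Wnt ligand, was also higher, at 148 against 1.89 CPM. The members that were lower were TCF7L1, a repressor of Wnt targets in stem cells, at 9.12 against 110.4 CPM, and the secreted Wnt antagonists SFRP1 at 30.5 against 241 CPM and SFRP2 at 93.0 against 399 CPM.

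All 13 measured HOX genes were at least 2-fold higher in primitive streak-like cells, with a median log2 fold of 4.46. HOXB1 was at 82.0 CPM (78.5 to 85.6) against 1.64 CPM (1.27 to 2.09), HOXB4 at 44.2 against 0.637 CPM and HOXB9 at 28.4 against 0.172 CPM. Among mesenchymal and matrix genes, 16 of 22 were higher and 0 lower. They included SNAI2 and ZEB2, repressors of epithelial genes, at 40.7 against 0.834 CPM and 27.2 against 0.711 CPM, and the cadherins CDH11 at 56.9 against 2.31 CPM and CDH2 at 171 against 15.9 CPM. Of 31 mesoderm and heart transcription factors, 13 were higher and 3 lower. CITED1 was at 134 against 1.89 CPM, TBX6, a gene of presomitic mesoderm, at 89.5 against 2.23 CPM, TBX3 at 49.9 against 0.613 CPM and FOXC1 at 18.2 against 0.368 CPM. The lower members included OTX2, an anterior homeobox gene, at 2.84 against 27.8 CPM and MYCN at 5.10 against 11.4 CPM. HES7, an oscillating gene of the segmentation clock, was at 112 against 1.32 CPM, and TTC29 at 53.4 against 0.515 CPM.

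The list of BMP, Nodal and TGF-beta genes went both ways, with 5 of 13 higher and 3 lower. FST, which binds activin, was at 149.9 against 11.3 CPM, BMP4 at 47.1 against 7.18 CPM, BAMBI, a decoy receptor, at 17.7 against 5.93 CPM, and BMP7 at 16.8 against 5.69 CPM. LEFTY1 and LEFTY2, inhibitors of Nodal, were lower at 0.474 against 7.99 CPM and 0.237 against 5.27 CPM, as was CYP26A1, which degrades retinoic acid, at 2.02 against 9.24 CPM. Of 24 chromatin modifiers, 5 were higher and 1 lower. Of 19 amino acid and endoplasmic reticulum stress genes, 3 were higher and 1 lower.

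On the lower side, 19 of 23 pluripotency-associated genes outside the markers were at least 2-fold lower in primitive streak-like cells and 0 higher. The median log2 fold was -2.37, against -0.27 to 0.23 for matched random lists. IDO1, which breaks down tryptophan, was at 0.593 CPM (0.332 to 0.977) against 39.6 CPM (37.7 to 41.6). The kinases LCK and PIM2 were at 4.54 against 52.1 CPM and 8.69 against 91.8 CPM, and DPPA2 at 0.750 against 14.8 CPM. Of 18 epithelial genes 11 were lower and 1 higher. The polarity gene CRB3 was at 1.11 against 14.8 CPM, the splicing factor ESRP1 at 6.40 against 46.8 CPM, the tight junction gene CLDN7 at 36.1 against 198 CPM and the cadherin CDH1 at 8.41 against 47.3 CPM. DSP, a desmosome gene, was the exception, at 243 against 60.2 CPM. The genes with the largest folds on this side included the noncoding transcripts RP11-587D21.5 at 4.34 against 255 CPM, RP4-792G4.2 at 6.44 against 317 CPM and RP4-590F24.2 at 7.50 against 158 CPM, and the small GTPase gene RAB17 at 2.84 against 116 CPM. PLA2G4C was at 1.26 against 66.4 CPM, HLA-DPB2 at 1.78 against 68.4 CPM, the metallothionein MT1X at 12.3 against 299 CPM, RASGRP2 at 3.44 against 81.5 CPM, and APELA, a peptide hormone of the apelin receptor, at 2.41 against 60.1 CPM. TNNI3, which encodes the troponin I of the adult heart, was higher in pluripotent-like cells, at 89.7 CPM (86.8 to 92.6) against 7.23 CPM (6.22 to 8.36).

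The lowest of these values lay close to background. Free RNA at 3.54% of UMIs in pluripotent-like cells would give DKK1 6.15 CPM and CDX1 0.894 CPM there, so the folds of such genes are limited by free RNA as well as by depth.

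**Figure D3:**
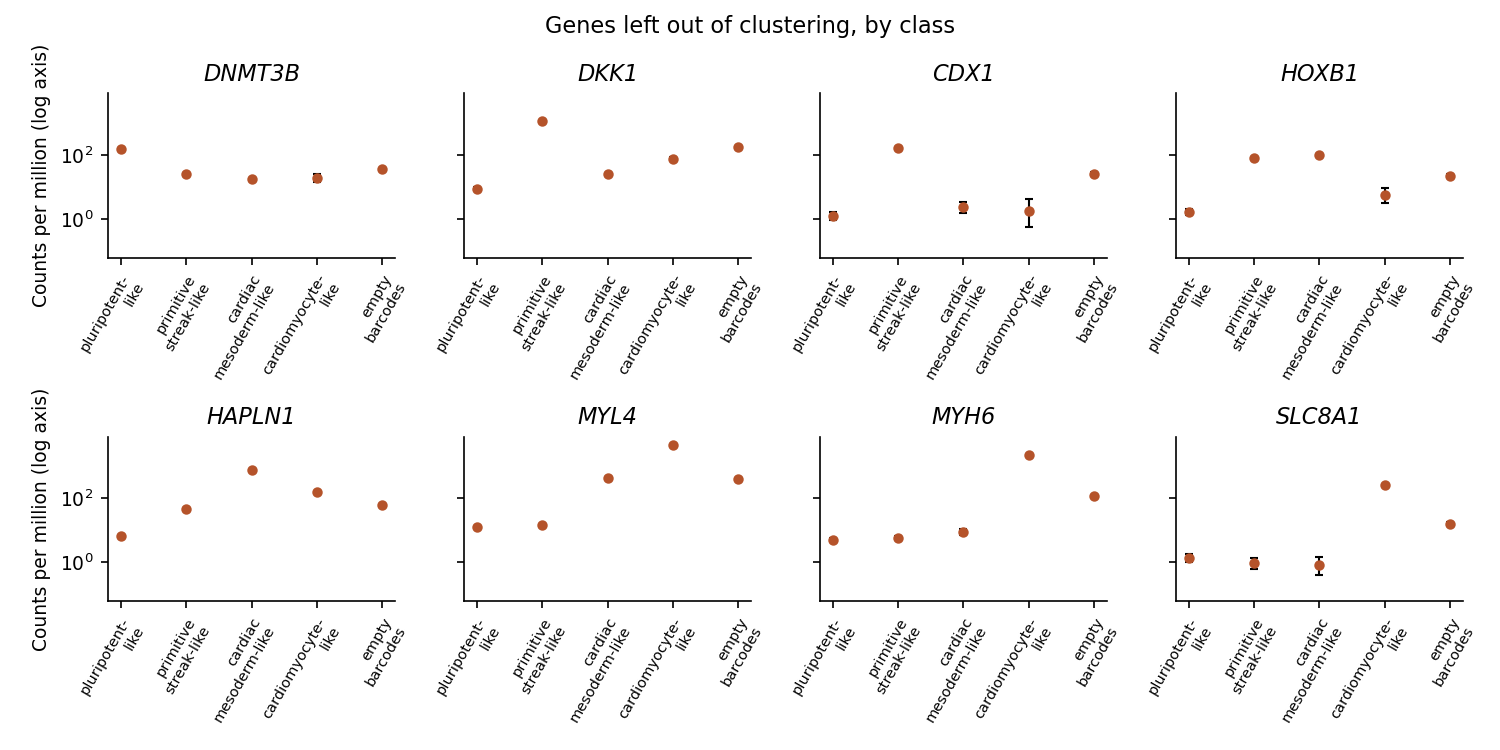
CPM on a log axis of 8 genes left out of clustering, in the 4 classes of the route and in empty barcodes, with exact 95% Poisson intervals that cover counting error only. DKK1 was at 1165 CPM in primitive streak-like cells, HAPLN1 at 783 CPM in cardiac mesoderm-like cells and MYH6 at 2227 CPM in cardiomyocyte-like cells.

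Cardiac mesoderm-like cells were set against primitive streak-like cells to ask what separates the class bearing cardiac mesoderm markers from the class placed before it on the assumed route. Of the measured Wnt feedback and target genes 19 of 28 were lower and 4 higher, and most measured genes of the BMP, Nodal and TGF-beta list and of the sarcomere list were higher. DKK1 was at 24.7 CPM (22.0 to 27.7) against 1165 CPM (1151 to 1178), 45.4-fold lower, and CDX1 at 2.31 CPM (1.53 to 3.33) against 167 CPM (162 to 172). ANKRD1, a muscle ankyrin repeat gene, was at 184 CPM (176 to 192) against 2.69 CPM (2.09 to 3.40). MYL4, the atrial and fetal light chain of myosin, was at 449 CPM (437 to 461) against 14.5 CPM (13.1 to 16.1). HAPLN1, which links hyaluronan to proteoglycans in the matrix, was at 783 CPM (768 to 799) against 48.0 CPM (45.3 to 50.8).

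Of 28 Wnt genes measured in this pair, 19 were at least 2-fold lower in cardiac mesoderm-like cells and 4 higher. The median log2 fold was -2.30, against -0.40 to 0.18 for matched random lists. The Wnt feedback gene NKD1 was at 5.11 against 115 CPM, DKK4 at 0.823 against 41.4 CPM and the Wnt-induced transcription factor SP5 at 1.73 against 61.5 CPM. SFRP5 was higher, at 34.8 against 0.948 CPM, as were TCF7L1 at 27.6 against 9.12 CPM, the R-spondin receptor LGR5 at 19.4 against 7.86 CPM and SFRP1 at 62.6 against 30.5 CPM. Other genes with large folds on the lower side were CITED1 at 2.63 against 134 CPM, CXCR4 at 5.60 against 211 CPM, the somatostatin receptor SSTR2 at 3.79 against 156 CPM, HES6 at 13.9 against 416 CPM, TAC1 at 2.22 against 88.9 CPM and TTC29 at 0.741 against 53.4 CPM.

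BMP, Nodal and TGF-beta genes were higher for 13 of 17 and lower for 3. CFC1, a co-receptor of Nodal, was at 74.2 CPM (69.4 to 79.2) against 0.513 CPM (0.273 to 0.878), LEFTY2 at 23.0 against 0.237 CPM, BMP5 at 33.8 against 2.25 CPM and CYP26A1 at 29.1 against 2.02 CPM. CFC1, and CCKBR named below, were among the 10 top genes of the smaller cardiac mesoderm-like cluster and not of the larger. FST was lower at 17.3 against 149.9 CPM, BMP7 at 2.06 against 16.8 CPM and GDF15 at 0.741 against 8.61 CPM. Among mesenchymal and matrix genes 11 of 26 were higher and 2 lower. TNC, a matrix glycoprotein, was at 109.8 against 3.32 CPM, PRRX1, a homeobox gene of mesenchyme, at 41.3 against 1.70 CPM, and the collagen COL6A3 at 10.5 against 0.553 CPM. SNAI1 and CDH2 were lower, at 20.1 against 57.3 CPM and 72.8 against 171 CPM. In the sarcomere list 9 of 14 measured members were higher and 0 lower. TPM1 was at 1479 against 238 CPM, TNNI1, the fetal troponin I, at 129 against 19.3 CPM, and NEBL at 34.5 against 5.37 CPM.

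Further genes with large folds included the signalling regulator RGS4 at 106 against 1.34 CPM, CCBE1, a secreted gene of lymphatic growth, at 64.8 against 1.03 CPM, and NR2F1, a nuclear receptor of atrial identity, at 55.1 against 0.869 CPM. CALB2, which encodes the calcium-binding protein calretinin, was at 78.1 against 1.70 CPM and the hormone receptor CCKBR at 51.3 against 0.790 CPM. SLC40A1, the iron exporter, was at 72.1 against 1.58 CPM and BST2, an antiviral membrane protein, at 556 against 20.1 CPM.

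Of 36 S phase genes 13 were at least 2-fold lower in cardiac mesoderm-like cells and 0 higher, with CCNE2 at 1.07 against 6.40 CPM, RRM2 at 32.4 against 105 CPM, CLSPN at 43.1 against 138 CPM and FEN1 at 52.5 against 161 CPM. G2 and M phase genes were lower for 4 of 44 and higher for 0, and their median log2 fold of -0.57 took the other sign with clustering genes drawn from all genes. An unnamed cluster of 136 cells, high in G2 and M phase genes, also held HAND1 and TMEM88. It lay outside the cardiac mesoderm-like class, which limits what these cell cycle counts show. Targets of p53 were lower for 9 of 12 and higher for 0. CDKN1A, which halts the cell cycle, was at 2.55 CPM (1.73 to 3.62) against 26.8 CPM (24.8 to 28.9), SESN1 at 5.02 against 31.0 CPM and PHLDA3 at 9.22 against 46.7 CPM. Immediate early and heat shock genes went both ways, with 9 of 18 higher and 3 lower. FOS was at 361 against 49.1 CPM, FOSB at 114 against 8.26 CPM, JUN at 253 against 39.1 CPM and JUND at 56.9 against 15.5 CPM, whereas IER3 was at 46.4 against 256 CPM and the chaperones HSPH1 and HSP90AA1 were at 31.0 against 122 CPM and 1160 against 2382 CPM. Atrial, ventricular and pacemaker genes were higher for 6 of 10 and lower for 3. Growth and imprinted genes were higher for 4 of 17 and lower for 1, and retinoic acid genes for 4 and 2 of 10.

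Immediate early genes such as FOS and JUN also respond to cell dissociation, and the pool gives no way to separate that response from the class. Free RNA at 5.43% of UMIs in cardiac mesoderm-like cells would give DKK1 9.44 CPM there. The nuclear RNA MALAT1, a clustering gene and a possible sign of RNA quality, was at 19030 against 3401 CPM. The median mitochondrial share was 3.07% against 4.03%. Whether the MALAT1 level reflects RNA quality or the class was not tested.

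Cardiomyocyte-like cells were set against cardiac mesoderm-like cells to ask what the last class of the assumed route held and lacked. Most measured sarcomere, calcium handling, glycolysis and hypoxia genes were higher, and HOX genes were lower. MYH6, the alpha myosin heavy chain, was at 2227 CPM (2173 to 2283) against 8.89 CPM (7.29 to 10.7), 225-fold higher. ACTC1, cardiac actin, was at 11320 CPM (11190 to 11440) against 150.1 CPM (143 to 157). SLC8A1, the sodium-calcium exchanger, was at 259 CPM (241 to 279) against 0.823 CPM (0.395 to 1.51). HOXB1 was at 5.58 CPM (3.19 to 9.06) against 101 CPM (95.7 to 107), 15.6-fold lower.

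All 28 measured sarcomere genes were at least 2-fold higher in cardiomyocyte-like cells, and 29 of all 30 listed. The median log2 fold was 5.50, and 5.55 with the member that had no UMI in cardiac mesoderm-like cells set at its bound. Matched random lists ran from -0.10 to 0.41. CSRP3, a sensor of stretch, was at 254 against 0.906 CPM, SMPX at 278 against 2.22 CPM, the light chain MYL3 at 604 against 6.34 CPM and the myosin-binding MYBPC3 at 97.6 against 0.494 CPM. MYL2, the ventricular light chain, had 11.5 CPM and no UMI in cardiac mesoderm-like cells. Against a floor of 3 counts over that class it was at least 46.6-fold higher. ASB2, part of a ubiquitin ligase of muscle, was at 109 CPM and rested on 3 UMIs in cardiac mesoderm-like cells, a ratio of 440.3 (interval 149 to 2147). MASP1, a protease of the complement pathway, was at 232 against 1.24 CPM.

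Of 18 measured calcium handling and ion channel genes, 14 were higher and 2 lower, with a median log2 fold of 2.43. Over all 24 listed genes 16 were higher. PLN, which restrains the calcium pump of the sarcoplasmic reticulum, was at 302 against 6.26 CPM, HRC at 119 against 3.71 CPM and the calcium channel CACNA1D at 31.0 against 0.576 CPM. GJA1, the main gap junction gene of the ventricle, was lower at 46.0 against 169 CPM, as was the potassium channel KCNJ3 at 2.09 against 6.01 CPM.

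Glycolysis genes were at least 2-fold higher in cardiomyocyte-like cells for 16 of 22 and lower for 0, with a median log2 fold of 1.59. The muscle enzymes PGAM2 and ENO3 were at 35.2 against 1.40 CPM and 425 against 100.0 CPM, the lactate exporter SLC16A3 at 210.2 against 17.0 CPM and hexokinase HK1 at 128 against 28.0 CPM. Hypoxia genes were higher for 15 of 18 and lower for 0. They included PDK1, which keeps pyruvate from the mitochondrion, at 273 against 29.0 CPM, the vessel growth factor VEGFA at 37.6 against 5.35 CPM, FAM162A at 381 against 78.6 CPM and BNIP3 at 328 against 71.7 CPM. Nuclear genes of oxidative phosphorylation were higher for 18 of 36 and lower for 0. ATP5G1 was at 567 against 157 CPM, COX7B at 723 against 217 CPM and CYCS, cytochrome c, at 584 against 202 CPM. COX6A2, the muscle form of a cytochrome oxidase subunit, was at 93.4 CPM and rested on 2 UMIs in cardiac mesoderm-like cells, a ratio of 567 (interval 156 to 4709). Of 13 transcripts of the mitochondrial genome 4 were at least 2-fold higher and 0 lower. Fatty acid oxidation genes were higher for 8 of 19 and lower for 0. FABP3, the fatty acid carrier of muscle, was at 173 against 2.47 CPM, the nuclear receptor ESRRG at 18.1 against 0.659 CPM and ACSL1 at 11.8 against 0.988 CPM. PPARGC1A, a regulator of mitochondrial content, was at 16.4 CPM and rested on 2 UMIs in cardiac mesoderm-like cells, a ratio of 99.5 (interval 26.1 to 846).

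All 12 measured HOX genes were at least 2-fold lower in cardiomyocyte-like cells, with a median log2 fold of -2.83. HOXB6 was at 2.44 against 51.7 CPM and HOXB5 at 5.93 against 54.8 CPM. HOXB8 had no UMI in cardiomyocyte-like cells and 9.80 CPM in cardiac mesoderm-like cells, at least 9.37-fold higher there against a floor of 3 counts over the class. Also lower were MEIS1, a partner of HOX proteins, at 12.9 against 70.2 CPM, CCBE1 at 5.93 against 64.8 CPM, the matrix gene TGFBI at 6.28 against 74.0 CPM, HAPLN1 at 159 against 783 CPM, VRTN at 10.1 against 63.3 CPM and LIX1 at 171 against 831 CPM. TNC was at 19.2 against 109.8 CPM, but its direction turned when the class took in other cells, with a log2 fold of 1.16 at a doubled UMI threshold and 1.28 at a mitochondrial limit of 10%.

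The cardiomyocyte-like class was the smallest on the route, with 2868541 UMIs, and its low levels carry wide counting intervals. MYH6 was at 117 CPM in empty barcodes, and free RNA would account for 6.36 of the 8.89 CPM seen in cardiac mesoderm-like cells. MALAT1 was at 33860 against 19030 CPM and MT-CO1 at 8979 against 5978 CPM.

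Pluripotent-like and cardiac mesoderm-like cells were compared directly for epithelial and mesenchymal genes. Most measured pluripotency-associated genes were higher in pluripotent-like cells, most measured mesenchymal and matrix genes were lower, and epithelial genes went both ways. VIM, the intermediate filament of mesenchymal cells, was at 277 CPM (272 to 282) against 6720 CPM (6674 to 6766), 24.2-fold lower. CDH1 was at 47.3 CPM (45.2 to 49.4) against 1.40 CPM (0.815 to 2.24), 20.1-fold higher. EPCAM, an epithelial adhesion gene, was at 229.9 against 13.3 CPM, ESRP1 at 46.8 against 1.56 CPM and CLDN7 at 198 against 6.50 CPM. MALAT1, named above as a possible sign of RNA quality, also differed in this pair. It was at 3866 CPM in pluripotent-like cells, below the cardiac mesoderm-like level given above.

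Of 26 measured mesenchymal and matrix genes 23 were at least 2-fold lower in pluripotent-like cells and 0 higher, with a median log2 fold of -2.75. HAPLN1 was at 6.55 against 783 CPM, PRRX1 at 0.270 against 41.3 CPM and TNC at 3.58 against 109.8 CPM. Of 23 measured pluripotency-associated genes 16 were at least 2-fold higher in pluripotent-like cells and 0 lower. Over all 26 found in the matrix 19 were higher. IDO1 was at 39.6 against 0.494 CPM, LCK at 52.1 against 1.65 CPM, PIM2 at 91.8 against 5.27 CPM and the neuropeptide galanin, GAL, at 416 against 29.1 CPM. Epithelial genes split, with 9 of 18 measured higher, 11 over all 20 listed, and 5 measured lower. The lower members were keratins and desmosome genes: KRT8 at 426 against 3040 CPM, KRT18 at 767 against 3202 CPM, KRT19 at 254 against 1834 CPM, DSP at 60.2 against 204 CPM and PKP2 at 9.91 against 88.5 CPM.

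The genes with the largest folds in pluripotent-like cells were again RP11-587D21.5 at 255 against 4.28 CPM, RP4-792G4.2 at 317 against 7.33 CPM, RP4-590F24.2 at 158 against 1.98 CPM, PLA2G4C at 66.4 against 1.48 CPM and HLA-DPB2 at 68.4 against 1.56 CPM. PLPP2 at 102 against 2.88 CPM, the kinesin KIF1A at 73.3 against 2.47 CPM and the neuronal calcium sensor VSNL1 at 76.9 against 2.96 CPM were also higher in pluripotent-like cells. Lower there were LIX1 at 8.34 against 831 CPM, RGS4 at 0.907 against 106 CPM, ANKRD1 at 2.67 against 184 CPM, SLC40A1 at 0.589 against 72.1 CPM, CFC1 at 0.515 against 74.2 CPM, HOXB1 at 1.64 against 101 CPM and the noncoding RP11-627G18.3 at 2.72 against 182 CPM. So were the homeobox genes MEIS1 at 0.687 against 70.2 CPM and MEIS2 at 2.58 against 139 CPM.

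Pluripotent-like and cardiomyocyte-like cells, the ends of the route, were compared for proliferation and energy metabolism. Most measured S phase genes were higher in pluripotent-like cells, and 10 of 19 measured fatty acid oxidation genes were higher in cardiomyocyte-like cells. HELLS, a chromatin remodeller of dividing cells, was at 190.3 CPM (186 to 195) against 44.3 CPM (36.9 to 52.7), 4.22-fold higher in pluripotent-like cells. MCM5, part of the replicative helicase, was at 101 CPM (98.1 to 104) against 25.1 CPM (19.6 to 31.6). FABP3 was at 18.5 CPM (17.2 to 19.9) against 173 CPM (158 to 188), 8.91-fold lower in pluripotent-like cells. MALAT1, a nuclear RNA and a possible sign of RNA quality, was at 3866 against 33860 CPM, and the mitochondrial MT-CO1 at 6072 against 8979 CPM.

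S phase genes were at least 2-fold higher in pluripotent-like cells for 24 of 36 and lower for 0, with DSCC1 at 38.4 against 7.32 CPM and CDC6 at 45.1 against 10.8 CPM. G2 and M phase genes were higher for 14 of 44 and lower for 0. DLGAP5 was at 85.5 against 20.9 CPM, CKS2 at 467 against 138 CPM, HMMR at 72.7 against 23.4 CPM and the checkpoint kinase BUB1 at 49.3 against 17.1 CPM. That count ran from 7 to 35 over the processing alternatives, and the median log2 fold was 0.82.

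Fatty acid oxidation genes were at least 2-fold lower in pluripotent-like cells for 10 of 19 and higher for 0. PPARGC1A was at 0.490 against 16.4 CPM, ESRRG at 0.662 against 18.1 CPM and ACSL1 at 1.86 against 11.8 CPM. Of 36 measured nuclear genes of oxidative phosphorylation 6 were lower and 0 higher. COX6A2 was at 2.75 against 93.4 CPM, NDUFB3 at 97.6 against 234 CPM, NDUFA1 at 231 against 520.5 CPM and COX7B at 350.2 against 723 CPM. This count was 1 at a doubled UMI threshold and at a mitochondrial limit of 10%, and 3 with totals taken without mitochondrial and ribosomal protein genes. Of 22 glycolysis genes 0 were at least 2-fold higher in pluripotent-like cells and 5 lower, among them ENO3 at 11.9 against 425 CPM, SLC16A3 at 28.0 against 210.2 CPM, PGAM2 at 5.66 against 35.2 CPM and the phosphofructokinase PFKP at 52.0 against 235 CPM. In cholesterol synthesis 1 of 18 was higher and 2 were lower, MVK at 10.6 against 51.2 CPM and SC5D at 33.1 against 95.5 CPM.

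The contractile genes of the cardiomyocyte-like class marked the largest folds of this pair. MYL4 was at 12.6 against 4782 CPM, ACTC1 at 51.2 against 11320 CPM, TNNI1 at 20.6 against 3970 CPM, ACTA2, smooth muscle actin, at 5.15 against 1648 CPM and ANKRD1 at 2.67 against 616 CPM. MYH6 was at 5.03 against 2227 CPM, MYL3 at 2.40 against 604 CPM, SMPX at 0.637 against 278 CPM, CSRP3 at 0.687 against 254 CPM and PLN at 0.956 against 302 CPM. On the other side SCGB3A2, a secretoglobin, was at 79.8 against 1.39 CPM, GAL at 416 against 16.4 CPM, GNG4 at 52.1 against 1.39 CPM, RAB17 at 116 against 4.88 CPM, CLDN7 at 198 against 6.28 CPM, PLA2G4C at 66.4 against 1.39 CPM, RP11-587D21.5 at 255 against 4.88 CPM, RP4-792G4.2 at 317 against 9.41 CPM and RP4-590F24.2 at 158 against 4.18 CPM. LCK was at 52.1 CPM and rested on 2 UMIs in cardiomyocyte-like cells, a ratio of 74.7 (interval 20.6 to 617).

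The classes off the route were each compared with all other kept cells. Definitive endoderm-like cells pooled 2 clusters, and the liver markers TTR (18150 against 31.4 CPM) and AFP (451 CPM against none) belonged to the larger of them. Over the class as a whole fibrinogen FGA was at 122 CPM (112 to 133) against 0.237 CPM (0.160 to 0.338) and the apolipoprotein APOB at 128 CPM (118 to 139) against 0.363 CPM (0.266 to 0.485). ALDH1A1, which makes retinoic acid, was at 205 against 1.32 CPM and the detoxifying enzyme GSTA2 at 111 against 0.379 CPM. All 11 measured HOX genes were lower there, and 11 of 19 BMP, Nodal and TGF-beta genes were higher and 6 lower. Endothelial-like cells held SOST, a secreted Wnt antagonist, at 960.4 CPM (898 to 1025) against 0.453 CPM (0.345 to 0.585), the endothelial sialomucin EMCN at 382 CPM (343 to 423) against 0.138 CPM (0.0820 to 0.219), GNG11 at 3604 against 24.2 CPM and HOPX at 597 against 3.26 CPM. Of 18 epithelial genes 16 were at least 2-fold lower in them and 0 higher. In the 20 blood-like cells the alpha globin HBA1 was at 1908 CPM (1757 to 2068) against 0.574 CPM (0.451 to 0.719), the delta globin HBD at 1297 against 0.306 CPM, ALAS2, which starts heme synthesis in red cells, at 382 against 0.749 CPM, and FERMT3, an integrin partner of blood cells, at 356 against 0.780 CPM.

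Fibroblast or stromal-like cells were high in matrix genes, with 17 of 27 mesenchymal and matrix genes higher and 2 lower. TGFBI was at 576 CPM (548 to 605) against 21.8 CPM (21.0 to 22.6), the matrix Gla protein MGP at 85.2 against 2.04 CPM, the complement gene C7 at 112 against 3.50 CPM and the cell cycle inhibitor CDKN2B at 128 against 3.63 CPM. S phase genes were lower for 23 of 35 in this class and higher for 0. Epicardial-like cells held IGFBP5, which binds insulin-like growth factors, at 1636 CPM (1609 to 1665) against 76.7 CPM (75.1 to 78.2), the water channel AQP1 at 109.7 against 2.77 CPM, the integrin ITGA3 at 104 against 4.48 CPM and the noncoding RP11-790G19.2 at 127 against 3.85 CPM. Calcium handling and ion channel genes were higher for 7 of 12 in epicardial-like cells and lower for 3.

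Neuroectoderm-like cells were high in DLK1, a ligand-like Notch regulator, at 3068 CPM (3028 to 3109) against 155 CPM (153 to 157), ZFHX4 at 138 against 9.45 CPM, the growth factor NRG1 at 60.6 against 5.19 CPM and FABP7, a fatty acid carrier of neural progenitors, at 125 against 14.3 CPM. Of 18 hypoxia genes 13 were higher there and 0 lower, and all 11 measured HOX genes were lower. Surface ectoderm or amnion-like cells held HPGD, which degrades prostaglandins, at 120.3 CPM (105 to 137) against 1.13 CPM (0.954 to 1.33), TMEM54 at 386 against 25.3 CPM, CYP26A1 at 205 against 19.2 CPM and SHISA2 at 87.7 against 8.74 CPM. Epithelial genes were higher for 10 of 19 in this class and lower for 0.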

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

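Each test in this part was chosen after the result was seen.

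Barcodes under the UMI threshold take no part in the comparisons, yet they held cardiomyocyte RNA above the background: MYH6 was at 401 CPM (382 to 421) in the 1868 barcodes from 1000 UMIs to the threshold, against 117 CPM in empty barcodes. The values argue against free RNA alone, since the median of 10 cardiomyocyte markers was 2.10 times the level in empty barcodes, with 7 more than 1.5 times as high, although of other contractile genes ACTC1 (602 against 624 CPM) and TNNI3 (49.6 against 65.7 CPM) were not higher. They also argue against barcodes of every class falling short alike, since 25.8% (20.8 to 31.3%) of 287 cardiomyocyte-like barcodes with at least 1000 UMIs lay under the threshold, against 11.4% (10.6 to 12.2%) of the other classes without pluripotent-like barcodes, which stood at 33.95%, though endothelial-like barcodes at 21.4% (13.9 to 30.5%) overlapped, and the 287 were 2 unlike clusters with 63 of 146 (MYH7 at 399 CPM) and 11 of 141 (MYH7 at 37.4 CPM) under the threshold. Open are damaged cells, in which MALAT1, a nuclear RNA, was 2.93 times and MT-CO1 2.39 times the level of kept cardiomyocyte-like cells, and a loss of cells rich in MYH7, the beta myosin heavy chain, which made up 14.9% (13.0 to 16.9%) of MYH6 and MYH7 under the threshold and 4.84% (4.34 to 5.38%) in kept cells. Free RNA held MYH7 at 21.2 CPM, 15.3% of MYH6 and MYH7, and MALAT1 at 13060 CPM, below the 1020 and 99140 CPM of these barcodes, and no biological explanation was tested because the design holds 1 group.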

How the results depend on the processing

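All 15 alternatives were planned and run, and with 1 sample no replicate could be left out. Of 3895 gene folds recomputed for 273 gene and comparison pairs, 3893 kept their direction, and 1799 lay inside the counting interval of the reported ratio. The 2 that turned were TNC in cardiomyocyte-like over cardiac mesoderm-like cells, with a log2 fold of 1.16 at a doubled UMI threshold and 1.28 at a mitochondrial limit of 10%. Under both settings the cardiomyocyte-like class took in cells of a cluster that has no name in the reported classes, 91 and 186 of them, the cluster led by PDLIM3, CCL2 and TCF21. The same cells give the cardiomyocyte-like share of 5.94% at the limit of 10%. Of 32 list medians of at least 0.5 on the log2 scale, 1 turned under any alternative, the G2 and M phase list in cardiac mesoderm-like over primitive streak-like cells with clustering genes drawn from all genes.

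The pluripotent-like share was 24.3% with 1000 UMIs per barcode and 21.8% at a doubled threshold. The primitive streak-like share was 13.2% and 17.7% under the same settings, 11.03% with clustering genes drawn from all genes and 11.4% at resolution 2.0, where 267 and 261 cells of its larger cluster lost their name. The cardiac mesoderm-like share was 6.75% at a doubled threshold, 8.10% without a mitochondrial limit and 8.07% with clustering genes drawn from all genes, where 162, 186 and 186 cells of its smaller cluster and 159, 94 and 109 of its larger cluster were unnamed. At the doubled threshold 26 and 113 cells of these clusters were not kept. The fibroblast or stromal-like share was 9.58% with 15 principal components, where 397 cells of the unnamed cluster of 803 took this name. It was 6.22% at resolution 0.5, where the 190 cells led by PDLIM3 took it. The surface ectoderm or amnion-like share was 3.49% at resolution 2.0. There, 135 cells of the unnamed cluster of 416 and 15 of the unnamed cluster led by CYP26A1 took that name. Unnamed cells ran from 20.6 to 32.8%. The number of G2 and M phase genes higher in pluripotent-like than cardiomyocyte-like cells was 28 with 1000 UMIs, 23 at a doubled threshold, 35 at a mitochondrial limit of 10%, 23 with doublets kept and 7 with a pseudocount of 10. The number of oxidative phosphorylation genes higher in cardiomyocyte-like cells was 1, 1 and 3 at a doubled threshold, at a limit of 10% and with totals without mitochondrial and ribosomal protein genes. List and step pairs with a median of at least 2-fold numbered 7 with a pseudocount of 10, which pulls low levels together. Beyond the changes in class membership given here, the cause was not tested.

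The counts of genes higher in the other planned comparisons stayed within 1.5 times of their reported value: sarcomere 27 to 29, calcium handling 12 to 17, Wnt 18 to 23, pluripotency-associated 15 to 21, epithelial 8 to 12, and mesenchymal and matrix 18 to 23. Kept cells ran from 5841 to 8467. The shift of log2 folds by scaling was largest at -0.25 in cardiomyocyte-like over cardiac mesoderm-like cells, with totals without mitochondrial and ribosomal protein genes, and 0.21 in cardiac mesoderm-like over primitive streak-like cells with median ratios. Depth limits the cardiomyocyte-like class most among the classes of the route, with 2868541 UMIs.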

Other observations

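The test on pluripotency-associated genes left out of clustering was chosen after the result was seen, while the MALAT1 ratio and the median over markers of other classes, both on low-mitochondrial barcodes, were chosen before.

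The 5 clusters without a name were compared with all other kept cells. The largest, with 803 cells (11.4%), held STAR, which moves cholesterol into the mitochondrion, at 148 CPM (141 to 155) against 9.89 CPM (9.33 to 10.5), the plasminogen activator PLAT at 119.9 against 16.01 CPM, GAP43, a gene of growing axons, at 191 against 35.4 CPM and LRRTM1 at 61.0 against 10.9 CPM. Cardiac mesoderm markers were also high in it, with TMEM88 at 903 CPM, HAND1 at 344 CPM and PDGFRA at 110 CPM. The larger cardiac mesoderm-like cluster had 1204, 430 and 156 CPM. KDR was further below that cluster, at 29.6 against 75.6 CPM, and the stromal marker LUM was above it, at 509 against 314 CPM. HOX genes were at least 2-fold higher for 7 of 12 there and lower for 2, and amino acid and endoplasmic reticulum stress genes higher for 7 of 19 and lower for 0. A cluster of 416 cells (5.92%) held CRABP1, a retinoic acid carrier, at 1640 CPM (1607 to 1673) against 178 CPM (175 to 179.9), VGF, a neuropeptide precursor, at 60.9 against 3.69 CPM, PLAU at 118 against 8.89 CPM and TFPI, an inhibitor of coagulation, at 258 against 27.6 CPM. Hypoxia genes were higher for 10 of 18 in it and epithelial genes lower for 14 of 18. A cluster of 190 cells (2.70%) held CYP26A1 at 225 CPM (209 to 242) against 16.5 CPM (15.8 to 17.2), DRAXIN, a guidance gene of axons, at 104 against 24.6 CPM, C5orf38 at 62.4 against 8.04 CPM and RP11-82C23.2 at 65.1 against 3.31 CPM, with mesenchymal and matrix genes lower for 19 of 25.

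Another cluster of 190 cells joined contractile and matrix genes. TNNT2, a cardiomyocyte marker, was at 1381 CPM there against 4207 CPM in cardiomyocyte-like cells. The other cardiomyocyte markers except SLN (54.6 against 25.1 CPM) were also lower, such as TTN at 129.9 against 2343 CPM and NKX2-5 at 3.61 against 314 CPM. Epicardial-like cells held TNNT2 too, at 723 CPM. Against that class, the epicardial marker TCF21 was higher in this cluster, at 352 against 111.5 CPM, and TBX18 lower, at 46.9 against 102.8 CPM. Sarcomere genes were higher than in all other cells for 13 of 21 and lower for 2, and mesenchymal and matrix genes higher for 19 of 27 and lower for 0. PDLIM3, a gene of the Z disc, was at 747 CPM (712 to 784) against 16.2 CPM (15.5 to 16.9), the activin subunit INHBA at 141 against 3.84 CPM, the water channel AQP3 at 253 against 8.10 CPM and C7 at 126 against 3.79 CPM. G2 and M phase genes were lower for 41 of 44 in this cluster, and S phase genes for 29 of 35. The remaining 136 cells (1.94%) stood out by mitosis, with 43 of 45 G2 and M phase genes higher, KIF14 at 105 CPM (92.2 to 119) against 12.7 CPM (12.1 to 13.3), PBK at 102 against 12.5 CPM, NEK2 at 135 against 17.5 CPM and MXD3 at 115 against 13.2 CPM. They also held TMEM88 at 880 CPM, HAND1 at 284 CPM and PDGFRA at 109 CPM. The larger cardiac mesoderm-like cluster had 1204, 430 and 156 CPM. KDR and APLNR were further below that cluster, at 21.6 against 75.6 CPM and 7.51 against 28.6 CPM.

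Within cardiomyocyte-like cells the counts lay mostly on TNNI1, the fetal troponin I, MYH6 and the light chain MYL7. MYL7 was a marker used to name this class and MYL2 was left out of clustering, so their shares depend in part on that choice. TNNI3 made up 4.49% (4.12 to 4.87%) of TNNI1 and TNNI3, MYH7 4.84% (4.34 to 5.38%) of MYH6 and MYH7, and MYL2 0.162% (0.112 to 0.227%) of MYL2 and MYL7. TNNI3 made up 14.5% of TNNI1 and TNNI3 over all kept cells. The cardiomyocyte-like shares are averages over the class, and their intervals do not show how cells differ within it. With at least 1000 UMIs per barcode, cardiomyocyte-like barcodes fell into unlike clusters. MYH7 was at 399 and MYH6 at 2443 CPM in the cluster of 146 barcodes. In that of 141 barcodes MYH7 was at 37.4 and MYH6 at 2886 CPM. These clusters include 63 and 11 barcodes under the UMI threshold, so the values are not those of kept cells alone.

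Among barcodes under the UMI threshold, 653 fell in a pluripotent-like group with few mitochondrial counts, at a median of 1571 UMIs and 0.74% mitochondrial UMIs, against 3.95% in kept pluripotent-like cells and 2.37% in empty barcodes. Free RNA alone is argued against: 21 pluripotency-associated genes left out of clustering had a median of 1.502 times the level in empty barcodes (quartiles 1.38 and 1.77), 17 of them with an interval above it and 0 below. The median over 52 markers of other classes was 0.549 times the level in empty barcodes, between the bounds of 0.5 and 0.8 set for that test, so by itself it did not decide. Bare nuclei cannot be told apart from other sources: MALAT1 was 2.45 times its level in kept pluripotent-like cells, between the bounds of 1.5 and 3 set for the test. At 9465 CPM it lay below the 13060 CPM of empty barcodes, so the ratio shows no MALAT1 beyond the level of free RNA. NEAT1, also a nuclear RNA, was lower than in kept pluripotent-like cells and in empty barcodes (9.89 against 24.8 and 21.0 CPM), ACTB was at 3524 against 3344 CPM in kept pluripotent-like cells and EEF1A1 at 8389 against 9268 CPM, and no biological explanation was tested.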
